A study of Mus musculus with 2 samples.

How the data were processed

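Small RNA reads from 2 heart libraries of female B6CASTF1/J mice aged 2 months had been counted per microRNA gene by the submitters. Per the labels, the reads were placed on the mouse assembly mm10, and the text deposited with the tables names release M21 of the GENCODE annotation. The aligner, the counting tool, their versions and the adapter trimming are not given in the sources used here. The deposited values are raw counts of reads per gene, with no normalization. Each table has no header and holds 3 count columns, which were identified from their values: reads on either strand, reads on the gene's own strand and reads on the opposite strand. The first 4 lines of a table name no gene and give unmapped, multimapping, no-feature and ambiguous reads. In the own-strand column they held 70.0% of the reads of replicate 1 and 65.3% of replicate 2, and they were left out of library sizes and tests. All 2202 gene identifiers matched the M21 annotation, which holds 2207 microRNA genes, and positions, host genes and hairpin sequences were taken from it.

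Both libraries form 1 group. The labels number them as biological replicates and as different females, but give both the same donor label, so they were taken as 2 animals without further evidence. The p-values between them test whether 2 libraries differ beyond counting error, and do not measure the spread between animals. Such a difference may be partly technical and is not an effect of any condition. A chi-square test over genes gave a statistic of 1138 per degree of freedom, so the libraries differed beyond counting error and the tables were not copies of each other. It cannot tell 2 animals from 2 preparations of 1 animal. Own-strand counts were scaled to CPM of their total per library, so that a library's microRNA genes share the same sum. A gene was called detected with at least 10 counts in both libraries. Means and SDs are over 2 libraries. Shares of counts per library carry 95% exact Clopper-Pearson intervals, and the limit for a count of 0 was set at 3 counts. Reads carry no molecular identifiers in these tables, so these ranges cover counting error only.

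Before the data were examined, 22 gene lists with 220 entries were fixed, covering cell types, sequence families, heart remodelling and 2 genomic clusters. Of these entries 219 matched a gene, 5 of them through an older symbol. The rule for the genes named in the text was also fixed then. It takes the 20 genes with the highest mean CPM, every detected member of the cardiac muscle, skeletal muscle, endothelium, smooth muscle and pericyte, fibroblast and erythroid lists, and the 2 most abundant members of each other list. It adds the 5 genes higher and the 5 lower in replicate 2 with the largest fold among those past the test with at least 100 counts over both libraries. This gave 57 genes. Mir1a-1, Mir133a-1 and Mir133a-2 fall outside it and were added after their values were seen.

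Differences between the libraries were tested per gene with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment at 0.05. Genes that also differed by at least 1.5-fold were counted beside it. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept alone and library totals as the scale. A list's median log2 ratio was set against 10000 random lists of detected genes, drawn within bins of mean CPM. Hairpins were searched for exact stretches of 20 bases shared with a hairpin at another locus, since the counting may drop their reads. The levels and folds of the 14 named genes with such a stretch are uncertain: Mir378a, Mir23a, Mir23b, Mir1a-2, Mir133b, Mir199b, Mir128-1, Mir138-1, Mir29c, Mir26a-2, Mir92-1, Mir411, Mir487b and Mir3074-1. Hairpins that overlap each other, such as Mir486 and Mir3107, were not compared, so bases shared within such a pair were not looked for. Alternatives were the either-strand column, other count filters, thinning to equal depth, TMM and DESeq2 factors, DESeq2's dispersion, other denominators, lists without some members, and each replicate alone.

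The binomial test was checked on simulated counts for replicate 2 against replicate 1 with 314 genes. It called 76 of 100 genes changed by 1.5-fold, 99 of 100 changed by 3-fold and 2 of 114 unchanged genes. The simulated counts held counting error alone, and the test on them was scaled by the unchanged genes, not by library totals. These rates therefore do not carry over to the real comparison, whose libraries differed by more than counting error. The dispersion fit was tested on simulated data of 306 genes in 5 runs per value, and returned 0.201, 0.402 and 0.588 for true coefficients of 0.2, 0.4 and 0.6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.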

Results

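Short RNA in the microRNA size range was sequenced from heart tissue of female B6CASTF1/J mice aged 2 months. These animals are the hybrid offspring of a C57BL/6J parent and a CAST/EiJ parent, so every autosome is present as 1 copy of each strain's sequence. The labels give 1 group with 2 biological replicates and no contrasting condition. The samples are numbered as different females of a tissue bank but carry the same donor label, so that they came from 2 animals is a reading of the labels. The data therefore give the level at which microRNA genes were counted in the heart, and how far 2 libraries differed. Reads that mapped to several places were counted for no gene. The data thus do not give the level, or the absence, of microRNAs from genes with copies elsewhere. Each library was given as read counts for 2202 annotated microRNA genes.

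Replicate 1 held 8069273 reads and replicate 2 held 7995058. Reads placed on a single microRNA gene, on its own strand, numbered 2424441 in replicate 1, or 30.0% of the library (95% exact Clopper-Pearson interval 30.0 to 30.1). In replicate 2 they numbered 2770301, or 34.7% (34.6 to 34.7). The largest class was reads that mapped to several places, 49.5% in replicate 1 and 42.7% in replicate 2, which were counted for no gene. A further 3.75% and 5.16% mapped once outside microRNA genes, and 16.7% and 17.5% were unmapped. At this depth 10 counts corresponded to 4.12 CPM (counts scaled to the library's total over microRNA genes) in replicate 1 and 3.61 in replicate 2, and a gene with 0 counts could have lain at up to 1.24 CPM in replicate 1 and 1.08 in replicate 2. All intervals and limits given here cover counting error only.

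**Figure D1:**
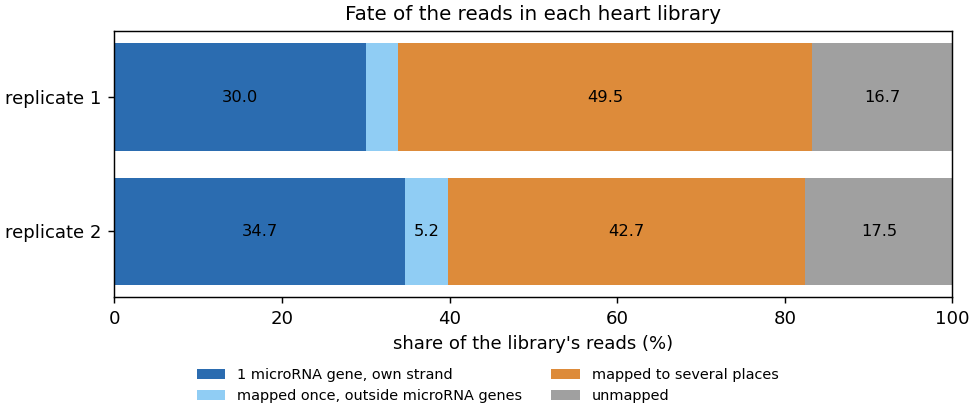
Horizontal bars show the share of each heart library's reads, in percent, by fate: own strand of 1 microRNA gene, mapped once outside microRNA genes, mapped to several places, and unmapped. Reads mapped to several places made up 49.5% of replicate 1 and 42.7% of replicate 2, more than the 30.0% and 34.7% that were counted for a microRNA gene.

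The heart's counted microRNA pool was led by Mirlet7i, a member of the let-7 family that restrains growth and developmental timing genes, at 105694 ± 2237 CPM (SD, n = 2). Mir378a followed at 98897 ± 6630 CPM; it lies in an intron of Ppargc1b, a coactivator gene of mitochondrial metabolism. Mirlet7g stood at 79847 ± 16983 CPM and Mir126a, the endothelial microRNA hosted by Egfl7, at 79461 ± 8214 CPM. The next were Mirlet7d (56338 ± 844 CPM), Mirlet7b (54867 ± 11942 CPM), the erythroid Mir451a (47322 ± 55869 CPM, a rank that rests on replicate 2, with 86827 CPM there and 7816 in replicate 1) and the smooth muscle Mir143 (46119 ± 3672 CPM). Mir23b and Mir23a, paralogs from 2 clusters, stood at 37338 ± 185 and 36224 ± 9379 CPM. These 10 genes together held 61.7% of counts in replicate 1 and 66.7% in replicate 2 (mean 64.2% ± 3.54, n = 2), and 35 of the 2202 genes held 90%.

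The genes ranked 11 to 20 were Mir22 (31799 ± 17764 CPM), Mir99a (27338 ± 12521), Mir139 (24394 ± 5057), Mir26b (20288 ± 9132), Mir149 (19932 ± 7422), Mir191 (11162 ± 36.9), Mir93 (10037 ± 683), Mir30d (9688 ± 583), Mir15b (9559 ± 2495) and Mir30a (8822 ± 1316 CPM). The SD between the libraries exceeded the mean for Mir451a alone among the 20 most abundant genes. In mm10, Mirlet7i lies on chromosome 10 at 122985640 to 122985724, in an exon of the transcript D630033A02Rik. Mir378a lies on chromosome 18 at 61397835 to 61397900, Mirlet7g on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82, and Mir126a on chromosome 2 at 26591357 to 26591429. Mir451a lies between genes on chromosome 11 at 78073170 to 78073241, and Mir143 on chromosome 18 at 61649196 to 61649258. Altogether 306 genes had at least 10 counts in both libraries (321 and 322 in each library alone), and 1520 had no count in either. Of the 1087 genes that share 20 bases with another hairpin 70 were detected, against 236 of the 1115 others. A low or absent count of the former may reflect uncounted reads. Mir378a, Mir126a, Mir451a and Mir191 overlap an annotated microRNA gene on the opposite strand, and their counts rest on the strand-specific column. Mir23a and Mir23b share an exact stretch of 20 bases with each other, and Mir378a with Mir378c. Some of their reads may therefore be uncounted, so their levels are uncertain.

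Heart muscle microRNAs encoded inside myosin genes were detected in both libraries. Mir208a, in an intron of the alpha myosin heavy chain gene Myh6 (mm10 chromosome 14, 54949060 to 54949142), stood at 3704 ± 3057 CPM. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), stood at 3497 ± 1211 CPM. Mir208b, in an intron of the beta myosin heavy chain gene Myh7 (chromosome 14, 54975700 to 54975776), stood at 61.7 ± 31.7 CPM, and Mir1a-2 at 58.2 CPM in replicate 1 and 24.2 CPM in replicate 2. Mir1a-1, Mir133a-1 and Mir133a-2, the other members of the cardiac muscle list, had at most 11 counts in a library. The list held 0.605% of counts in replicate 1 (exact interval 0.595 to 0.615) and 0.858% in replicate 2 (0.847 to 0.869). All Mir1a and Mir133a genes share a stretch of 20 bases with a hairpin at another locus, and reads that mapped to several places were not counted, so these levels are uncertain.

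The ratio of Mir208a to Mir208b counts was 18.3 in replicate 1 (exact interval 15.9 to 21.2) and 149 in replicate 2 (123 to 182). Both libraries thus had more Mir208a than Mir208b, with a geometric mean ratio of 52.3. The ratio differed 8.13-fold between them, since Mir208a was 3.80-fold higher in replicate 2 (3.67 to 3.94) and Mir208b was 2.14-fold lower.

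Among lists for the heart's other cell types, the endothelium list had the highest mean, 8.26% ± 0.789 of counts (n = 2), although in replicate 2 the erythroid list was higher (9.57% against 8.82%). Mir126a made up 96.2% of it; Mir221 stood at 3009 ± 278 CPM and Mir222 at 114 ± 46.9 CPM. The smooth muscle and pericyte list held 4.76% ± 0.435, of which Mir143 made up 96.9%, while Mir145a from the same cluster stood at 1475 ± 674 CPM. The fibroblast list held 1.13% in replicate 1 and 0.259% in replicate 2, and Mir21a made up 85.0% of it. Its detected members were Mir21a (5914 ± 5805 CPM, in an exon of Vmp1), Mir214 (911 ± 297), Mir152 (122 ± 73.3) and Mir199b (10.7 ± 2.37 CPM, uncertain for bases shared with the Mir199a genes). Mir199a-1 (0 and 1 counts) and Mir199a-2 (7 and 9 counts) were not detected, and both share bases with other hairpins, so their levels are uncertain. The erythroid list held 1.16% in replicate 1 (exact interval 1.14 to 1.17) and 9.57% in replicate 2 (9.53 to 9.60), and Mir451a made up 88.3% of its mean share. Counted on both strands together, the order of the lists changed, with smooth muscle at 6.36%, erythroid at 0.609% and endothelium at 0.418%, because reads over opposite-strand genes then belong to no gene.

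Within the erythroid list, Mir451a and Mir144, which form 1 cluster needed for red cell maturation, were 11.1-fold and 3.49-fold higher in replicate 2. Mir486, hosted by the ankyrin gene Ank1 and known in both red cells and muscle, stood at 1814 ± 148 CPM, and the opposite-strand gene Mir3107 at 68.0 ± 4.22 CPM. Bases shared between these overlapping genes were not looked for, so their levels are uncertain. The leukocyte list held 0.704% ± 0.131, with 6 of its 7 genes detected. Mir155, induced in activated immune cells, stood at 2057 ± 43.2 CPM, and the lymphocyte-enriched Mir150 at 1616 ± 398 CPM.

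Lists for tissues outside the heart held smaller shares of counts. The skeletal muscle list held 0.0219% ± 0.00756 of counts, nearly all from Mir206 (215 ± 75.7 CPM), with Mir133b, which shares bases with the Mir133a genes, at 4.23 ± 0.146 CPM. The epithelium list held 0.0370% ± 0.00147, led by Mir200c (214 ± 77.6 CPM) and Mir203 (95.1 ± 62.0 CPM). The neuron list held 0.0346% ± 0.0142, led by Mir128-1 (176 ± 125 CPM) and Mir138-1 (44.5 ± 2.89 CPM). Of its 15 genes 14 share 20 bases with another hairpin, the Mir124a, Mir9, Mir128 and Mir138 genes among them, so this low share is uncertain and may reflect uncounted reads; without them the list held 0.00432%. The liver list held 0.00289% ± 0.00163, all from the liver microRNA Mir122 (28.9 ± 16.3 CPM). None of the 14 genes of the pluripotent stem cell list reached 10 counts in both libraries, and the list held 24 counts in replicate 1 and 29 in replicate 2.

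**Figure D2:**
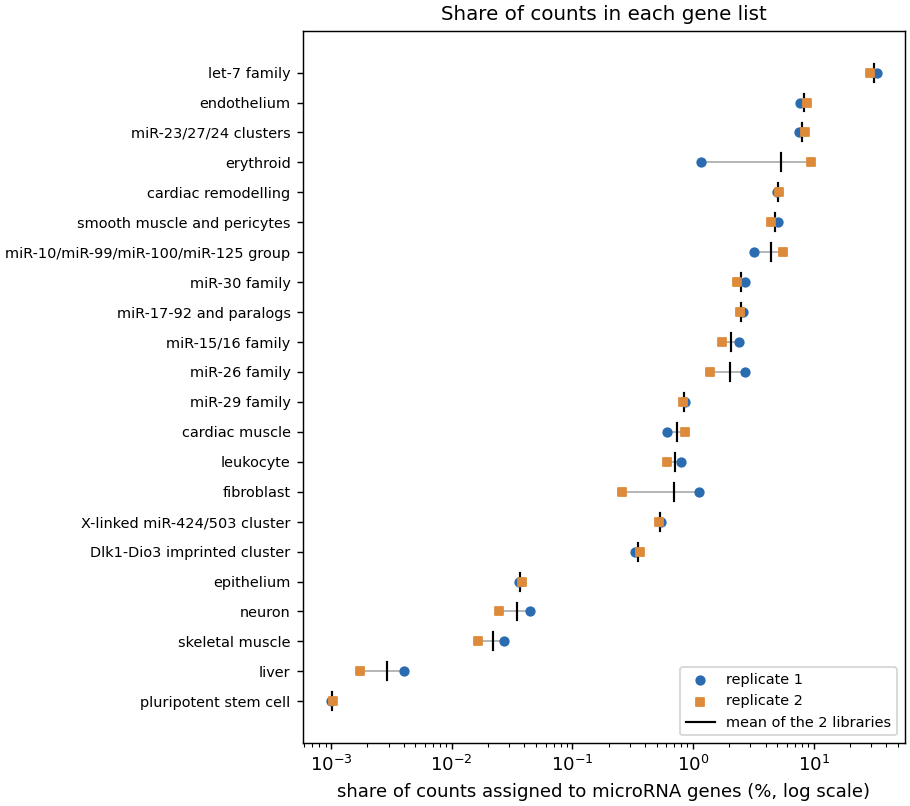
Each row is a gene list, and the horizontal axis (log scale) gives its share of the counts assigned to microRNA genes, in percent; circles are replicate 1, squares replicate 2, and the vertical tick is their mean. The let-7 family lies farthest right at 31.5%, and the erythroid list shows the widest gap between the libraries, from 1.16% to 9.57%.

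The let-7 family was the largest of the sequence families, with 31.5% ± 3.17 of counts and 13 of 14 genes detected. Next came the clusters of miR-23, miR-27 and miR-24 with 8.02% ± 0.566, a share that rests wholly on genes with shared bases (7 of 7) and is uncertain, and the group of miR-10, miR-99, miR-100 and miR-125 with 4.42% ± 1.69, led by Mir99a and Mir99b (5377 ± 4771 CPM). The miR-30 family held 2.52% ± 0.259, miR-17-92 and its paralogs 2.51% ± 0.0947, the miR-15/16 family 2.07% ± 0.485 and the miR-26 family 2.05% ± 0.936. Each family holds genes with shared bases, among them 6 of 14 in let-7, 2 of 3 in miR-26 and 3 of 4 in miR-29. Their reads may be uncounted, so the shares and the order of the families are uncertain. In the polycistron of miR-17-92, known for its role in proliferation, Mir92-1 stood at 4652 ± 1393 CPM, uncertain for bases shared with Mir92-2. The miR-29 family, whose members repress collagen genes, held 0.850% ± 0.0211, and Mir29a at 7596 ± 6.23 CPM exceeded Mir29c at 859 ± 201 CPM; Mir29c shares bases with Mir29b-1. Mir26a-2 stood at 337 CPM in replicate 1 and 21.7 CPM in replicate 2. The list of 14 genes reported in cardiac remodelling held 5.11% ± 0.144, of which Mir23a made up 70.9%, and 1.48% without genes that share bases. With reads mapped to several places in the denominator, each share would be lower, for example 12.9% for the let-7 family. That follows by arithmetic, since those reads were added to no gene. Reads of the family's own genes may be among them, so the lower shares are not more complete estimates.

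Comparison of the 2 libraries asked how far the profile held from 1 sample to the other. Mir451a showed the largest difference upward in replicate 2, 11.1-fold (exact interval 10.9 to 11.3). It was followed by Mir185 at 7.30-fold (6.59 to 8.12), Mir3074-1 at 6.73-fold (3.98 to 12.1), Mir99b at 4.37-fold (4.24 to 4.51) and Mir208a. In the opposite direction, Mir26a-2 was 15.6-fold lower in replicate 2 (817 and 60 counts) and Mir21a, a microRNA abundant in fibroblasts, was 5.54-fold lower. Mir487b of the imprinted Dlk1-Dio3 cluster was 5.35-fold lower, the myeloid Mir223 5.25-fold lower and Mir140, hosted by Wwp2, 4.31-fold lower. Each of these 10 genes passed a two-sided exact binomial test on counts with Benjamini-Hochberg adjustment over 306 genes; the largest adjusted p among them was 3.4e-18, for Mir3074-1. Mir26a-2 shares 20 bases with Mir26a-1, Mir487b with Mir376b and Mir3074-1 with Mir24-2, and Mir3074-1 also lies opposite Mir24-1, so the folds of these 3 genes are uncertain.

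**Figure D3:**
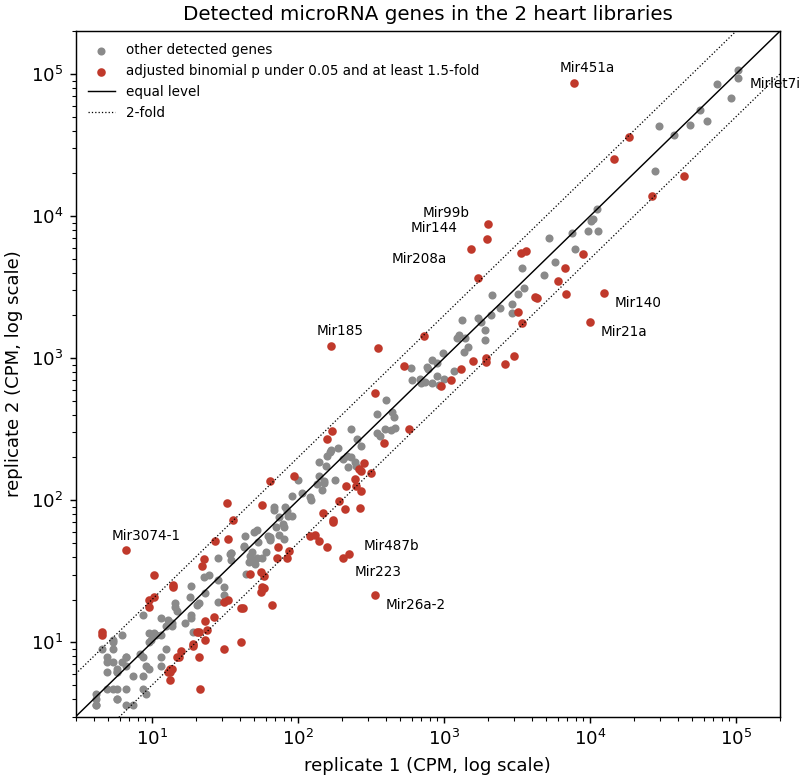
Each point is 1 of the 306 detected microRNA genes, with its level in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis (CPM, both log scales); the solid line marks equal level and the dotted lines a 2-fold difference. The 112 genes in red passed the exact binomial test with at least a 1.5-fold difference, and Mir451a lies farthest above the line and Mir26a-2 farthest below it.

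Across the 306 detected genes, Pearson's r of log2(CPM + 1) between the libraries was 0.974 and Spearman's rho 0.964, computed across genes, which are not independent replicates. The log2 ratio of replicate 2 over replicate 1 had an SD of 0.83, and 249 genes (81.4%) lay within 2-fold. By the binomial test 187 genes (61.1%) differed beyond counting error, 112 of them by at least 1.5-fold, with 34 higher and 78 lower in replicate 2. The median gene had a log2 ratio of -0.19, and folds given here are not corrected for it. TMM factors moved it to 0.03 and gave 52 higher and 46 lower, and DESeq2 factors moved it to 0 and gave 48 higher and 49 lower. The biological coefficient of variation, from edgeR's common dispersion, was 0.383 (bootstrap interval over genes 0.340 to 0.422), and 0.186 as the square root of DESeq2's median gene-wise dispersion. These tests compare 2 libraries and no conditions.

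By list, all 4 detected cardiac muscle genes differed by at least 1.5-fold, with Mir208a higher in replicate 2 and Mir499, Mir208b and Mir1a-2 lower. Mir499 was 1.65-fold lower, and under 1.5-fold with TMM or DESeq2 factors. In the fibroblast list 3 of 4 detected genes were lower in replicate 2, namely Mir21a, Mir152 (2.48-fold) and Mir214 (1.60-fold, under 1.5-fold with either factor set), and Mir199b did not pass the test (30 and 25 counts). Of 13 detected genes of the cardiac remodelling list 8 were lower and none higher, or 5 lower and 1 higher with either factor set. Its median log2 ratio of -0.71 lay at percentile 0.48 of 10000 random lists matched on expression. The fibroblast and cardiac muscle medians lay at percentiles 2.40 and 2.72, and the erythroid median at 99.2, each of its own random lists. Random lists drew genes independently, but Mir451a and Mir144 form 1 cluster and Mir486 and Mir3107 overlap, so the erythroid genes are not separate draws. The cardiac muscle list's share of counts was higher in replicate 2 (0.858%) than in replicate 1 (0.605%), against its median. Percentiles were computed for 17 lists without adjustment, and the other 13 lay between 5.44 and 87.5. The remodelling list holds Mir21a and Mir214 of the fibroblast list and Mir208b of the cardiac muscle list, so these are not separate results. Of the leukocyte genes 3 of 6 were lower, and 1 with either factor set. Of the let-7 family 3 of 13 were lower, but 1 was higher and none lower with either factor set, so no direction held for it. No gene of the miR-30 family both passed the test and differed by at least 1.5-fold under any of the 3 scalings. Adjusted over the list alone, the counts of these lists did not change.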

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

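The tests of explanations in this part were chosen after the low counts had been seen. No biological explanation of these counts was tested, since the labels give a single group. The test of shared copies asked for p under 0.05 over all families. Versions with a family left out and with families pooled were added after its result was seen, and a stricter rule, p under 0.05 whichever family is left out, was tried then, not met and not kept.

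Reads that mapped to several places were set aside by the counting, and their number is far above the 3 reads that a count of 0 allows: 3992614 in replicate 1 and 3410568 in replicate 2. The pattern that goes with them is the low counts of Mir1a-1 (6 and 5 counts), Mir1a-2 (141 and 67), Mir133a-1 (11 and 5) and Mir133a-2 (5 and 9), genes whose mature products are textbook abundant microRNAs of heart muscle. Counting on the wrong strand is argued against, since the 4 genes had 14 opposite-strand counts against 249 on their own strand. Loss of reads shared between identical copies is a candidate explanation: all 4 genes share 20 bases with another locus, and the difference in mean log2(CPM + 1) between genes with and without such a stretch, averaged over 7 sequence families, was -3.40 (permutation within families, 100000 resamples, two-sided p = 0.028). The difference was negative in 6 of the 7 families and 1.02 in miR-15/16; with 1 family left out the average ran from -4.14 to -2.38, with p from 0.011 to 0.091 by the same permutation test and under 0.05 in 4 of 7 runs, and pooled over 21 and 39 genes it was -2.05 (p = 0.068). The miR-23, miR-27 and miR-24 clusters could not enter the test, since all their genes have such a stretch. Their levels ran from 37338 CPM for Mir23b to 25.5 CPM for Mir3074-1. What stays open is how many of the reads set aside came from these genes, which the tables do not say, a lower expression of genes with copies for another reason, and an effect of CAST/EiJ sequence variants against mm10.

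Reads that mapped once outside microRNA genes numbered 302782 in replicate 1 and 412466 in replicate 2, and no comparison used them. Opposite-strand counts of genes with no annotated microRNA gene opposite totalled 78 in replicate 1 and 100 in replicate 2, or 0.00409% and 0.00509% of those genes' own-strand counts. Among them, Mir130a had 34 and 32 opposite-strand counts beside 7069 and 6632 on its own strand. Mir122 had 18 and 22 opposite-strand counts beside 98 and 48 on its own strand, above the limit of 3 in both libraries.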

How the results depend on the processing

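The run without Mir451a and Mir144 (SD of the log2 ratio 0.79) and the one with the median gene at a ratio of 1 (182 genes differing, 97 by at least 1.5-fold) were chosen after seeing the data. A filter of any count above 0 gave 682 genes detected and an SD of 1.26; at least 100 counts gave 182 detected and 65 genes differing by at least 1.5-fold, by construction. DESeq2's median gene-wise dispersion gave a coefficient of variation of 0.186; the cause was not tested. Counts on either strand moved the lists for cardiac muscle to 0.984%, endothelium to 0.418%, smooth muscle to 6.36% and let-7 to 41.3%, since opposite-strand pairs drop out; 8 of 57 named genes were then undetected, Mir378a, Mir126a and Mir451a included. Without the most abundant gene in the denominator, the endothelium list held 9.24%, smooth muscle 5.32% and let-7, which loses that gene, 23.4%. With multimapping reads in it the values were 26.6% for the 10 most abundant genes, 0.306% for cardiac muscle, 3.43% for endothelium, 1.95% for smooth muscle and 12.9% for let-7, and no number of genes reached 90%. These values fall by arithmetic, since no gene gains the multimapping reads, and are not more complete estimates. Without their top member, the cardiac muscle, endothelium, smooth muscle and let-7 lists held 0.361%, 0.312%, 0.148% and 20.9%. Mir451a and Mir21a made up 88.3% and 85.0% of the erythroid and fibroblast lists, which without them moved by less than their wide SD. Of the 16 other lists, 10 were higher by more than their SD on either strand, 9 without the top gene in the denominator, 16 were lower without their top member and with multimapping reads, and 7 without genes that share bases. TMM and DESeq2 factors cannot move the SD; each ended the call of 3 named genes (Mir499, Mir206, Mir214), added Mir23a and left 53 as they were, while 10 uncalled genes changed sign under some setting. Either library alone stays within 1 SD by arithmetic, and gives no spread, test or coefficient of variation. No paired analysis was possible because there is 1 group. Depth limits genes near 10 counts.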

Other observations

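Of the tests in this part, that of blood was chosen after the result was seen, and those of GC content and of neighbouring genes before. The labels give a single group, so no difference between groups was tested. Genes named here outside the rule were chosen after their values were seen.

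The imprinted Dlk1-Dio3 cluster on chromosome 12, whose microRNAs are transcribed from the maternal copy, held 0.347% ± 0.0270 of counts (n = 2), with 34 of the 59 listed genes on that chromosome detected. Mir496b, also in the list, lies on chromosome 19 and had no counts. Mir127, which lies opposite the paternally expressed Rtl1, led it at 1078 ± 493 CPM, followed by Mir411 at 455 ± 72.4 CPM, which shares bases with Mir758. Mir127 was 1.96-fold higher in replicate 2 and 6 other genes of the cluster were lower by at least 1.5-fold (5 adjusted over the list alone, and 4 with TMM or DESeq2 factors). The X-linked cluster of Mir322 and Mir503 held 0.532% ± 0.0163. In it, Mir322, the rodent counterpart of miR-424, stood at 4331 ± 712 CPM and Mir503, 200 bases away, at 65.7 ± 30.7 CPM, while Mir351 was 3.35-fold higher in replicate 2.

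Detected genes that neighbour each other on the same strand within 10 kb, and so can share a primary transcript, often differed in counted level. Over 88 such pairs the median difference in level was 4.79-fold, and 33 pairs differed by at least 10-fold while 23 differed by less than 2-fold. In 34 of these pairs at least 1 gene shares 20 bases with another hairpin, so its level is uncertain. The other 54 pairs had a median of 3.52-fold, with 17 at 10-fold or more and 16 under 2-fold, against 8.21-fold in the 34. Mir29a (7596 ± 6.23 CPM) exceeded Mir29b-1 (26.4 ± 9.29 CPM) 287-fold, and Mir143 exceeded Mir145a 31.3-fold. In the cluster of Mir23b on chromosome 13, Mir27b stood at 4827 ± 2826 CPM and Mir24-1 at 121 ± 38.1 CPM. Mir29b-1, Mir27b and Mir24-1 share 20 bases with other hairpins, so their levels are uncertain. Adapter ligation and size selection can act on each mature sequence by itself, and their part in these differences was not tested.

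The 2 libraries of the group differed beyond counting error in 187 of 306 genes by the binomial test. GC content of the whole hairpin is argued against as the cause, since a straight line on it took away 0.566% of the SD over 182 genes (Spearman's rho 0.10, permutation p = 0.18). GC content of the mature sequences was not tested, because the counts do not separate them. No difference shared along a cluster, as a change in a primary transcript would give, was seen: neighbours differed by a median of 0.63 on the log2 scale, 1.02 times the 0.62 of shuffled genes (permutation p = 0.55, one-sided, 130 genes). The test cannot exclude such a difference. Its 88 pairs include genes near 10 counts and 34 pairs with shared bases, where counting error or uncounted reads could hide it. Also open are a difference that acts on each mature sequence by itself, such as adapter ligation or size selection, and a difference between the animals, neither of which was tested.

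Mir451a and Mir144 were higher in replicate 2, by 3.66 and 2.00 on the log2 scale relative to the median gene. More blood in the tissue of replicate 2 is a hypothesis for this, and the data cannot decide it: the other erythroid genes, Mir486 and Mir3107, lay at 0.36 and 0.064 relative to the median gene, and both come from a locus that muscle also expresses, which could hide a rise. Bases shared between Mir486 and Mir3107, which overlap, were not looked for, so their levels are also uncertain. The median of the leukocyte genes lay at -0.38, at percentile 5.44 of random lists matched on expression, with members on both sides of the median gene, from Mir223 at -2.20 to Mir342 at 0.22. The ratio of Mir451a to Mir144 counts was 3.98 in replicate 1 and 12.7 in replicate 2, so the 2 genes of the cluster did not move by the same factor.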
